A study of Mus musculus with 600 samples.

How the data were processed

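RNA sequencing libraries from 4 tissues of male C57BL/6N mice were analysed. Per the labels, mice were 8 weeks old when the experiments started, total RNA was extracted with Trizol (RIN above 7.0), and 600 libraries were sequenced on an Illumina Novaseq. The labels name Bowtie 0.12.2, HISAT2 2.0, StringTie 1.3.0 and the GRCm38 genome build. The authors deposited 4 gene tables, each with raw read counts and FPKM (fragments scaled to transcript length and library total) for 150 libraries. The deposited count columns hold whole-number read counts with no normalization by the authors stated, and all 600 were used. The 600 FPKM columns were left out, since the count-based tests take depth into account. Gene positions are those of the deposited tables. How reads shared by close paralogs were assigned is not stated, which bears on Cyp4a10 and Cyp4a14, Scd1 and Scd3, Hspa1a and Hspa1b, Mt1 and Mt2, Serpina1e, Selenbp2, Amd2, Hist2h2aa1 and the Pcdhg genes.

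The tables name no tissue. Each was assigned its tissue from marker genes (Alb, Acta1, Adipoq and Ucp1), which is a reading of the values rather than of a label. Every test stays within a single table, so a wrong tissue would rename results and not change them. Columns named IF and IR were read as EODF and EODR. The number in a column name was read as hours after ZT12, also for AL. Over 19 clock genes, AL profiles read this way correlated with the other regimens at r from 0.32 to 0.92 across genes and times within a tissue, and at -0.35 to -0.85 when the number was read as ZT. Genes are not independent replicates, so no p is given for these. In 3 of the tables the replicate numbers match no label, and ranks 1 to 5 were used for leaving out replicates and for a block. The labels do not say whether tissues of 1 number came from 1 mouse.

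Genes with at least 1 CPM in at least 5 of a tissue's 150 libraries were tested, 14465 in liver, 14346 in muscle, 17511 in IngWAT and 16042 in BAT. The liver table lists 33987 genes and the others 55450. The test was edgeR 4.0.16 (TMM scaling, quasi-likelihood F test) with 1 mean for each of the 30 groups of a tissue. Each of the 7 contrasts averaged the 6 differences at equal time, and each regimen was also compared with AL at each time. SEs are those implied by the F statistic. The p-values were adjusted by Benjamini-Hochberg over the genes of each contrast, and genes with an adjusted p below 0.05 are counted, with the number changed by at least 1.5-fold beside them. The plan made before the files were read named limma on log2 FPKM values, and the counts found beside them led to edgeR instead, so the planned test on FPKM itself was not run. limma on log2(CPM + 1) is among the alternatives.

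Rhythm was tested in edgeR with a mean, cosine and sine of 24 h period per regimen, and a difference of rhythm by the differences of both harmonic terms. Peak times and amplitudes are harmonic fits to group means of log2(CPM + 1), with intervals at 95% from 1000 bootstrap resamples of libraries within groups. Sampling every 4 h with 5 libraries per time limits these. In the regimens other than AL, a 24 h rhythm cannot be separated from the hours of fasting or refeeding.

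The 22 gene lists were PPAR target genes, mitochondrial fatty acid oxidation, de novo lipogenesis, cholesterol biosynthesis, gluconeogenesis and amino acid catabolism, bile acid synthesis and transport, FoxO, ubiquitin ligase and autophagy genes, glucocorticoid-responsive genes, core clock genes, thermogenesis and brown adipocyte genes, ER chaperones and heat shock proteins, ATF4 and amino acid response, ribosome biogenesis, oxidative phosphorylation, lipolysis and adipocyte genes, cell cycle, extracellular matrix and fibroblast genes, and markers of macrophages, lymphocytes, erythroid cells, hepatocytes and skeletal muscle. They were tested against the other genes with limma 3.58.1 camera (preset correlation 0.01) on log2(CPM + 1), with an estimated correlation beside it, adjusted over all 616 tests. fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes, was run too. The lists, contrasts, thresholds (with FPKM in place of CPM) and the rule for naming genes were fixed before the data were examined. That rule ranked genes on log2(FPKM + 1). The edgeR ratios were ranked here instead, a change made after the files were opened.

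The rule named, for each contrast and tissue, the 3 largest rises and 3 largest falls at an adjusted p below 0.05, a mean of at least 5 CPM (5 FPKM in the plan) and the same sign at 5 or more of the 6 times, 168 in all. Predicted genes and mitochondrial, Mup and haemoglobin genes were passed over. Arntl, Dbp and the other clock genes were listed in advance. The expected number of genes moving the same way in 4 tissues assumes independent lists.

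Alternatives were a pseudocount of 0.1, no filter on low values, a filter on mean CPM of at least 1, median-ratio scaling, a replicate block, leaving out each replicate, and fitting only the 2 regimens compared. Chosen after seeing the data were limma on log2(CPM + 1), DESeq2 1.42.0, leaving out the neural library, and markers of other tissues as a covariate. The covariate was lipolysis and adipocyte genes in muscle, lymphocyte and skeletal muscle markers in IngWAT, and skeletal muscle markers in BAT. Each count was also computed for 100 splits of the libraries between the 2 regimens, drawn within each time, with the limma form of the test (for rhythm within a regimen, times were permuted).

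The pipeline was tested on simulated data made from the liver counts. Of 50 genes changed 1.2-fold, 9 were recovered, with 40 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, and 12 of 14265 unchanged genes were called. Of 50 genes given a rhythm difference of amplitude 0.2, 1 was recovered, with 15 at 0.5, 41 at 1 and 49 at 2, and 5 of 14265 others were called. Pairs of libraries within groups were checked for duplicates, and the smallest mean chi-square per gene between 2 libraries was 38.4. Work was done in R 4.3.3 with data.table (version 1.17.8), and in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.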

Results

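RNA was measured by sequencing in 600 libraries from male C57BL/6N mice, 150 from each of liver, skeletal muscle, inguinal white adipose tissue (IngWAT) and brown adipose tissue (BAT). The mice were under 5 feeding regimens. AL mice ate freely. AF mice had a single fast of 4 to 24 h, and AR mice fasted once for 24 h and were then refed for 4 to 24 h. EODF and EODR mice went through 15 cycles of every-other-day fasting, and were taken 4 to 24 h into a fasting day (EODF) or a feeding day (EODR). All switches were at Zeitgeber time (ZT) 12, so ZT16, 20, 0, 4, 8 and 12 stand for 4, 8, 12, 16, 20 and 24 h of fasting or refeeding. Each of the 120 groups of 1 tissue, regimen and time had 5 libraries. The labels do not say whether the regimens were matched for age at sampling.

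Total counts per library ran from 42908266 to 73340738 in liver, 50696521 to 86203110 in muscle, 47965875 to 78620487 in IngWAT and 52518090 to 85188327 in BAT. The count tables name no tissue, so each table was given its tissue from marker genes. Median CPM (counts scaled to library totals) were 73500 for Alb in the liver table, 47500 for Acta1 in the muscle table, 2190 for Adipoq in the IngWAT table and 2750 for Ucp1 in the BAT table. A single muscle library, EODF at ZT20 library 1, carried neural RNA, with Kif5a at 2640 CPM against a median of 0.339 in the other libraries and Acta1 at 205 against 47600. It is called the neural library here, and muscle results are also given without it.

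Ratios below are log2 ratios averaged over the 6 times, each regimen against the other at equal time, with their SE. CPM values are means with their SD over n = 30 libraries per regimen, a spread that includes the time of day. For counts of libraries, each library was compared with the other regimen's mean at its time. Of the 168 genes named by the rule (fixed in advance apart from its measure), 98 moved in the stated direction in 30 of 30 libraries. Their largest adjusted p was 0.012 for the 168. The rule picked these genes from the same libraries by ratio, p and sign, so such counts are no separate support. For low genes the range over the alternative settings is given where it left 1.5 times the ratio, and a setting that ended a call is named beside the gene. For each contrast and tissue, the 2 gene lists with the smallest adjusted p are given, and any other whose call held with an estimated correlation. Counts of list genes were the same adjusted over the list alone unless stated. List genes cited as examples had the largest ratios among members not yet named for that contrast.

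The comparison of AF with AL asked what a single fast changed. In liver 7580 genes differed (3866 up and 3714 down, 1493 by at least 1.5-fold). The largest rises were Cyp4a14 5.93 ± 0.18, Cyp4a10 4.21 ± 0.16 and Mt2 3.84 ± 0.36, and the largest falls Thrsp -3.86 ± 0.27, Hsd3b5 -2.95 ± 0.23 (lower in 24 of 30 libraries) and Pcsk9 -2.76 ± 0.22. Transcripts of Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) averaged 6470 ± 4170 CPM in AF and 78.1 ± 39.2 in AL, higher in 30 of 30 libraries (adjusted p = 1.4e-59). PPAR target genes were higher: 18 of 19 rose and 1 fell, median 1.94 (adjusted p = 2.1e-22, adjusted p = 0.035 with an estimated correlation), with Fgf21 4.50 ± 0.31 and Cyp4a31 3.77 ± 0.16. Cholesterol biosynthesis genes were lower: 1 of 24 rose and 23 fell, median -1.32 (adjusted p = 4.8e-17, adjusted p = 0.17 with an estimated correlation), with Sqle -2.28 ± 0.22 and Fdps -2.25 ± 0.21. In muscle 8207 genes differed (4229 up and 3978 down, 2476 by at least 1.5-fold), and 8932 (4278 up, 4654 down, 2491 by at least 1.5-fold) without the neural library. Rises were led by Depp1 4.04 ± 0.17, Doc2b 3.65 ± 0.20 and Trim63 3.63 ± 0.13, and falls by Slc2a5 -3.91 ± 0.67 (-4.24 to -1.27 over the alternatives), Nmrk2 -3.74 ± 0.19 and Klhdc7a -3.28 ± 0.93 (-4.65 to -0.86 over the alternatives, call lost with limma, with a pseudocount of 0.1 and without replicate 2). The ubiquitin ligase gene Trim63 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629) averaged 3840 ± 1970 CPM in AF and 265 ± 53.6 in AL, higher in 29 of 30 libraries (adjusted p = 3.3e-50). Of the FoxO, ubiquitin ligase and autophagy genes 20 of 22 rose and 1 fell, median 1.49 (adjusted p = 1.1e-18, adjusted p = 0.0049 with an estimated correlation), with Fbxo32 3.13 ± 0.14 and Sesn1 2.69 ± 0.09. Glucocorticoid-responsive genes rose alongside: 13 of 14 rose and 0 fell, median 1.5 (adjusted p = 6.8e-12, adjusted p = 0.018 with an estimated correlation), with Ddit4 3.14 ± 0.17 and Mt2 2.40 ± 0.19.

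In IngWAT 10154 genes differed (4974 up and 5180 down, 2800 by at least 1.5-fold). Zim1, Nr4a3 and Zc3h11a rose most (Zim1 3.72 ± 0.15, Nr4a3 3.56 ± 0.23 and Zc3h11a 3.39 ± 0.68 (1.37 to 4.90 over the alternatives, higher in 14 of 30 libraries, call lost without replicate 2)), and Ppp1r3b -3.72 ± 0.16, Slc2a5 -3.68 ± 0.15 and Acly -3.39 ± 0.12 fell most. ATP citrate lyase, Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000), averaged 327 ± 311 CPM in AF and 2740 ± 1180 in AL, lower in 29 of 30 libraries (adjusted p = 2.1e-51). De novo lipogenesis genes fell: 1 of 20 rose and 18 fell, median -1.64 (adjusted p = 1.1e-18, adjusted p = 0.038 with an estimated correlation), with Pnpla3 -2.81 ± 0.08 and Acss2 -2.71 ± 0.11. So did cholesterol biosynthesis genes: 0 of 23 rose and 22 fell, median -1.19 (adjusted p = 1.6e-16, adjusted p = 0.052 with an estimated correlation), with Ldlr -2.06 ± 0.10 and Fdps -2.03 ± 0.10. FoxO, ubiquitin ligase and autophagy genes rose: 17 of 22 rose and 4 fell, median 0.77 (adjusted p = 2.8e-08, adjusted p = 0.024 with an estimated correlation), with Fbxo31 2.42 ± 0.09 and Irs2 2.29 ± 0.09. The list holds Trim63 and Fbxo32, abundant in muscle fibres, and the Acta1 median in IngWAT was 85.1 CPM in AF against 32.4 in AL. In BAT 10071 genes differed (4805 up and 5266 down, 3192 by at least 1.5-fold). The extremes were Slc7a8 4.52 ± 0.15, Fbxo31 3.52 ± 0.12 and Trim63 3.44 ± 0.37 upward and Hephl1 -4.26 ± 0.26 (-4.34 to -2.15 over the alternatives), Slc2a5 -3.93 ± 0.15 and Fer1l6 -3.71 ± 0.18 downward. The Acta1 median in BAT was 850 CPM in AF against 880 in AL. The amino acid transporter gene Slc7a8 (ENSMUSG00000022180, chromosome 14, 54722209 to 54781946) averaged 145 ± 119 CPM in AF and 4.19 ± 1.61 in AL, higher in 29 of 30 libraries (adjusted p = 2.3e-54). Lower lists were cholesterol biosynthesis (1 of 23 rose and 20 fell, median -1.23 (adjusted p = 1.8e-13, adjusted p = 0.055 with an estimated correlation)) and de novo lipogenesis (1 of 20 rose and 18 fell, median -1.21 (adjusted p = 6.4e-13, adjusted p = 0.055 with an estimated correlation)), with Scd2 -3.04 ± 0.33 and Acly -2.68 ± 0.10. The FoxO list was higher: 19 of 22 rose and 1 fell, median 1.06 (adjusted p = 5.2e-12, adjusted p = 0.0056 with an estimated correlation).

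**Figure D1:**
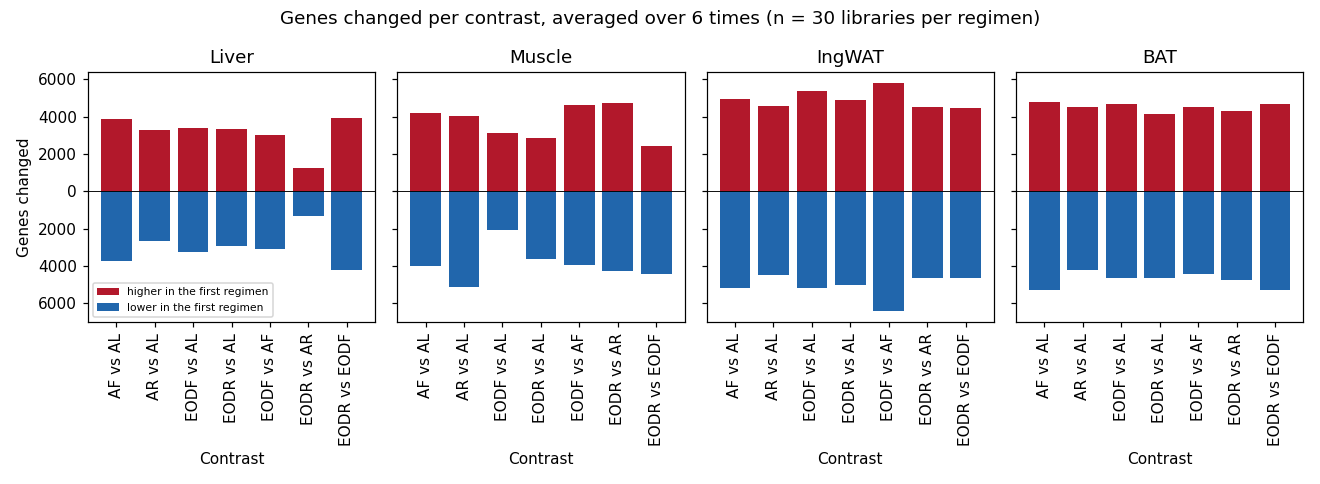
Genes changed in each contrast (bars, higher upward and lower downward; vertical axis, number of genes) in each tissue, from 30 libraries per regimen. IngWAT EODF against AF had the tallest bars (12200 genes) and liver EODR against AR the shortest (2569 genes).

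AR against AL asked which changes a day of refeeding left or brought. In liver 5918 genes differed (3268 up and 2650 down, 767 by at least 1.5-fold). Cyp4a14 stayed far above AL, with Cyp4a14 5.55 ± 0.17, Apoa4 4.39 ± 0.18 and Tubb2b 3.70 ± 0.62 (2.46 to 4.52 over the alternatives, higher in 24 of 30 libraries) highest and Scd1 -2.25 ± 0.16, Fabp5 -2.04 ± 0.18 and Selenbp2 -1.93 ± 0.20 lowest. Apolipoprotein A4, Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459), averaged 2830 ± 1180 CPM in AR and 128 ± 37.3 in AL, higher in 30 of 30 libraries (adjusted p = 1.2e-44). For mitochondrial fatty acid oxidation genes 13 of 18 rose and 2 fell, median 0.27 (adjusted p = 3.2e-05, adjusted p = 0.41 with an estimated correlation), with Cpt1b 1.48 ± 0.33 and Acadm 0.67 ± 0.06. For hepatocyte markers 0 of 11 rose and 8 fell, median -0.23 (adjusted p = 0.00011, adjusted p = 0.13 with an estimated correlation), with Ttr -0.38 ± 0.05 and Ambp -0.36 ± 0.03. In muscle 9190 genes differed (4052 up and 5138 down, 2946 by at least 1.5-fold), and 9656 (4527 up, 5129 down, 2926 by at least 1.5-fold) without the neural library. Heat shock genes headed the rises (Hspa1b 3.39 ± 0.17, Hspa1a 3.37 ± 0.17 and Egln3 3.13 ± 0.17), and Chac1 -3.64 ± 0.22, Nrep -3.16 ± 0.10 and Nmrk2 -2.98 ± 0.19 fell most. The developmental gene Nrep (ENSMUSG00000042834, chromosome 18, 33437019 to 33464029) averaged 20.1 ± 7 CPM in AR and 157 ± 38.1 in AL, lower in 30 of 30 libraries (adjusted p = 4.1e-57). Oxidative phosphorylation genes were lower: 0 of 34 rose and 31 fell, median -0.31 (adjusted p = 1.7e-05, adjusted p = 0.74 with an estimated correlation), with Sdhd -0.67 ± 0.06 and Ndufa5 -0.53 ± 0.05. The share of counts on mitochondrial genes was 8.07% in AR and 10.6% in AL. Ribosome biogenesis genes were higher: 14 of 20 rose and 2 fell, median 0.42 (adjusted p = 2e-05, adjusted p = 0.074 with an estimated correlation), with Polr1b 0.72 ± 0.04 and Gnl3 0.66 ± 0.07.

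In IngWAT 9055 genes differed (4563 up and 4492 down, 2302 by at least 1.5-fold). Rises were largest for Masp1 3.37 ± 0.17, Rgs16 2.99 ± 0.15 and Pcdhga9 2.89 ± 0.63 (1.34 to 3.31 over the alternatives, higher in 15 of 30 libraries), and falls for Nnat -3.66 ± 0.24, Mylk4 -3.15 ± 0.70 (-4.11 to -1.43 over the alternatives, call lost without replicate 3 or 4) and Mycl -2.74 ± 0.19. Mylk4 is a muscle-fibre gene, and the Acta1 median was 23.4 CPM in AR against 32.4 in AL. Neuronatin, Nnat (ENSMUSG00000067786, chromosome 2, 157560078 to 157562504), averaged 23.5 ± 33.9 CPM in AR and 179 ± 64.5 in AL, lower in 30 of 30 libraries (adjusted p = 1.2e-27). Lipid synthesis lists were above AL after refeeding. For cholesterol biosynthesis 20 of 23 rose and 1 fell (20 and 2 adjusted over the list alone), median 0.67 (adjusted p = 2.4e-12, adjusted p = 0.11 with an estimated correlation), with Cyp51 1.60 ± 0.12 and Ldlr 1.59 ± 0.09. For de novo lipogenesis 17 of 20 rose and 1 fell, median 0.77 (adjusted p = 1.5e-10, adjusted p = 0.15 with an estimated correlation), with Acly 1.71 ± 0.11 and Mlxipl 1.61 ± 0.07. Ribosome biogenesis genes rose too: 17 of 20 rose and 1 fell, median 0.41 (adjusted p = 2e-09, adjusted p = 0.038 with an estimated correlation). In BAT 8704 genes differed (4517 up and 4187 down, 2200 by at least 1.5-fold). The 3 largest rises were genes of hepatocytes, Alb 3.55 ± 0.66 (1.59 to 4.31 over the alternatives, higher in 23 of 30 libraries, no p from DESeq2), Apoa1 3.31 ± 0.67 (0.94 to 3.87 over the alternatives) and Serpina1b 3.18 ± 0.66 (0.92 to 3.82 over the alternatives, higher in 24 of 30 libraries). Alb exceeded 10 times the BAT median in 5 of 30 AR libraries and in 0 of 30 AL libraries, with a highest value of 2270 CPM. Falls were largest for Mfsd2a -3.36 ± 0.30, Nnat -2.94 ± 0.24 and Mycl -2.70 ± 0.19 (-2.91 to -1.59 over the alternatives). The transporter gene Mfsd2a (ENSMUSG00000028655, chromosome 4, 122946850 to 122961188) averaged 8.6 ± 12.6 CPM in AR and 58.8 ± 46.1 in AL, lower in 29 of 30 libraries (adjusted p = 8.8e-19). Every list gene of mitochondrial fatty acid oxidation was lower: 0 of 18 rose and 18 fell, median -0.70 (adjusted p = 6.3e-20, adjusted p = 0.052 with an estimated correlation), with Etfdh -1.01 ± 0.05 and Acadl -0.95 ± 0.05. The same held for oxidative phosphorylation: 0 of 34 rose and 34 fell, median -0.45 (adjusted p = 1e-18, adjusted p = 0.17 with an estimated correlation). The share of mitochondrial counts in BAT was 16.9% in AR against 23.5% in AL, and the Acta1 median 1770 CPM against 880.

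EODF against AL asked how a fasting day after repeated cycles differed from free feeding. In liver 6627 genes differed (3404 up and 3223 down, 1155 by at least 1.5-fold). Cyp2b9, Fmo3 and Cyp4a14 rose most (Cyp2b9 7.25 ± 0.51, Fmo3 6.60 ± 0.46 (3.37 to 6.75 over the alternatives) and Cyp4a14 5.76 ± 0.18), and Serpina1e -4.71 ± 0.24, Selenbp2 -4.42 ± 0.22 and Serpina12 -4.29 ± 0.28 fell most. The cytochrome gene Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661) averaged 88.5 ± 83 CPM in EODF and 0.593 ± 0.444 in AL, higher in 29 of 30 libraries (adjusted p = 1.9e-25). PPAR target genes were again higher: 17 of 19 rose and 1 fell, median 1.92 (adjusted p = 1e-18, adjusted p = 0.05 with an estimated correlation), with Cyp4a10 3.83 ± 0.15 and Cyp4a31 3.58 ± 0.16. Genes of ER chaperones and heat shock proteins were lower: 0 of 20 rose and 18 fell (0 and 19 adjusted over the list alone), median -0.70 (adjusted p = 8.5e-16, adjusted p = 0.02 with an estimated correlation), with Sdf2l1 -1.5 ± 0.12 and Manf -1.27 ± 0.10. In muscle 5211 genes differed (3129 up and 2082 down, 1061 by at least 1.5-fold), and 5579 (2771 up, 2808 down, 883 by at least 1.5-fold) without the neural library. Rises were Atp1a3 4.08 ± 0.37 (3.53 without the neural library), Actc1 3.54 ± 0.22 (3.58 without the neural library) and Acot1 2.81 ± 0.17 (2.80 without the neural library), and falls Hist2h2aa1 -5.18 ± 1.64 (-5.12 without the neural library, -10.00 to -0.76 over the alternatives, lower in 24 of 30 libraries, call lost with limma, with a pseudocount of 0.1 and without replicate 2, 3 or 5), Amd2 -3.12 ± 0.41 (-3.08 without the neural library) and Ifi27l2a -2.28 ± 0.26 (-2.24 without the neural library). Cardiac actin, Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548), averaged 6610 ± 2970 CPM in EODF and 641 ± 322 in AL, higher in 28 of 30 libraries (adjusted p = 9.2e-29, adjusted p = 7.9e-38 without the neural library). PPAR target genes rose: 12 of 14 rose and 0 fell, median 1.0 (adjusted p = 7.4e-11, adjusted p = 0.11 with an estimated correlation and adjusted p = 2e-13 without the neural library). Glucocorticoid-responsive genes rose as well: 10 of 14 rose and 0 fell, median 0.42 (adjusted p = 2.3e-05, adjusted p = 0.14 with an estimated correlation and adjusted p = 1.5e-05 without the neural library).

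In IngWAT 10510 genes differed (5366 up and 5144 down, 3260 by at least 1.5-fold). The 3 highest ratios were Actc1 4.17 ± 0.89 (0.70 to 5.74 over the alternatives, higher in 10 of 30 libraries, call lost with limma, with a pseudocount of 0.1 and without replicate 2 or 3), Atp1a3 3.01 ± 0.15 and Mogat2 2.76 ± 0.14 and the 3 lowest Cyp2f2 -4.63 ± 0.14, Mybpc1 -4.02 ± 0.76 (-4.24 to -1.31 over the alternatives, call lost without replicate 4) and Ifi27l2a -3.82 ± 0.11. Expression of Cyp2f2 (ENSMUSG00000052974, chromosome 7, 27119909 to 27133660) averaged 3.59 ± 1.52 CPM in EODF and 120 ± 55.9 in AL, lower in 30 of 30 libraries (adjusted p = 6.9e-61). Actc1 and Mybpc1 are striated muscle genes, and the median of Acta1 in IngWAT was 32.4 CPM in AL and 6.28 in EODF. Macrophage markers were lower: 0 of 14 rose and 14 fell, median -0.93 (adjusted p = 8.3e-09, adjusted p = 0.19 with an estimated correlation), with Itgax -1.68 ± 0.23 and Itgam -1.59 ± 0.19. In contrast to AF, de novo lipogenesis genes were above AL: 15 of 20 rose and 2 fell, median 0.60 (adjusted p = 1.8e-06, adjusted p = 0.33 with an estimated correlation), with Elovl6 1.64 ± 0.13 and Scd1 1.62 ± 0.11. In BAT 9284 genes differed (4668 up and 4616 down, 2456 by at least 1.5-fold). Actc1, Atp1a3 and Pck2 were the highest (Actc1 5.08 ± 0.36, Atp1a3 2.92 ± 0.15 and Pck2 2.29 ± 0.09), and Actc1 was at 4.34 with skeletal muscle markers as a covariate. Lowest were Dio2 -4.20 ± 0.25, Mfsd2a -3.37 ± 0.31 and Ackr3 -2.74 ± 0.12. Type 2 deiodinase, Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438), averaged 11.9 ± 10.7 CPM in EODF and 220 ± 135 in AL, lower in 30 of 30 libraries (adjusted p = 8.3e-32). Extracellular matrix and fibroblast genes rose: 18 of 20 rose and 0 fell, median 0.50 (adjusted p = 9e-06, adjusted p = 0.33 with an estimated correlation), with Fbn1 0.92 ± 0.12 and Col1a1 0.75 ± 0.10. Cell cycle genes rose: 15 of 17 rose and 0 fell (16 and 0 adjusted over the list alone), median 0.73 (adjusted p = 2.9e-05, adjusted p = 0.21 with an estimated correlation), with Cdk1 3.44 ± 0.23 and Ccnb1 3.20 ± 0.23.

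EODR against AL asked the same of a feeding day. In liver 6230 genes differed (3320 up and 2910 down, 947 by at least 1.5-fold). The genes at the extremes were those of the fasting day, with Cyp2b9 7.91 ± 0.51, Fmo3 6.53 ± 0.46 (2.98 to 6.71 over the alternatives) and Cyp4a14 4.97 ± 0.17 highest and Serpina1e -4.94 ± 0.25, Selenbp2 -4.37 ± 0.22 and Serpina12 -3.27 ± 0.26 lowest. The antitrypsin gene Serpina1e (ENSMUSG00000072849, chromosome 12, 103946931 to 103958975) averaged 598 ± 418 CPM in EODR and 16700 ± 3890 in AL, lower in 30 of 30 libraries (adjusted p = 3.1e-37). FoxO, ubiquitin ligase and autophagy genes were lower: 2 of 21 rose and 13 fell, median -0.32 (adjusted p = 9.9e-05, adjusted p = 0.15 with an estimated correlation), with Cebpd -0.65 ± 0.11 and Fbxo31 -0.62 ± 0.11. Lymphocyte markers were lower: 0 of 7 rose and 6 fell (0 and 7 adjusted over the list alone), median -0.63 (adjusted p = 0.00044, adjusted p = 0.13 with an estimated correlation), with Cd4 -1.94 ± 0.17 and Ighm -1.23 ± 0.14. In muscle 6436 genes differed (2840 up and 3596 down, 1166 by at least 1.5-fold), and 7398 (3693 up, 3705 down, 1140 by at least 1.5-fold) without the neural library. The ratios were highest for Actc1 3.6 ± 0.22, Atp1a3 3.29 ± 0.37 and Abca4 2.65 ± 0.14, and lowest for Hist2h2aa1 -6.22 ± 1.99 (-13.49 to -0.39 over the alternatives, lower in 22 of 30 libraries, call lost with limma, with a pseudocount of 0.1 and without replicate 2, 3 or 5), Chac1 -3.24 ± 0.21 and Amd2 -2.72 ± 0.40. Retinal transporter gene Abca4 (ENSMUSG00000028125, chromosome 3, 122044443 to 122180123) averaged 10.4 ± 3.5 CPM in EODR and 1.75 ± 0.665 in AL, higher in 30 of 30 libraries (adjusted p = 8.5e-34). For cholesterol biosynthesis 17 of 23 rose and 0 fell (18 and 1 adjusted over the list alone), median 0.60 (adjusted p = 3.9e-09, adjusted p = 0.19 with an estimated correlation), with Sqle 1.47 ± 0.19 and Lss 1.26 ± 0.19. For de novo lipogenesis 15 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), median 1.18 (adjusted p = 2.4e-07, adjusted p = 0.33 with an estimated correlation), with Acly 1.96 ± 0.29 and Elovl6 1.89 ± 0.35.

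In IngWAT 9904 genes differed (4901 up and 5003 down, 2778 by at least 1.5-fold). Rises were led by Hephl1 3.57 ± 0.17, Oxtr 3.48 ± 0.16 and Mogat2 3.14 ± 0.14, and falls by Cyp2f2 -4.73 ± 0.14, Mylk4 -3.92 ± 0.89 (-4.35 to -1.32 over the alternatives, call lost without replicate 3) and Trim63 -3.90 ± 1.16 (-6.32 to -0.77 over the alternatives, call lost with limma and without replicate 3 or 4). The oxytocin receptor gene Oxtr (ENSMUSG00000049112, chromosome 6, 112473683 to 112489943) averaged 202 ± 50.9 CPM in EODR and 21.9 ± 10.8 in AL, higher in 30 of 30 libraries (adjusted p = 3.9e-42). Mylk4 and Trim63 are expressed in muscle fibres, and the Acta1 median was 9.28 CPM in EODR against 32.4 in AL. Cholesterol biosynthesis genes were higher: 22 of 23 rose and 0 fell, median 1.29 (adjusted p = 5e-23, adjusted p = 0.02 with an estimated correlation), with Mvd 2.49 ± 0.12 and Lss 2.05 ± 0.10. All members of the de novo lipogenesis list were higher: 20 of 20 rose and 0 fell, median 1.13 (adjusted p = 5.4e-18, adjusted p = 0.043 with an estimated correlation), with Acly 1.88 ± 0.12 and Fads2 1.87 ± 0.08. In BAT 8823 genes differed (4163 up and 4660 down, 2071 by at least 1.5-fold). Highest were Actc1 3.79 ± 0.34, Ttr 3.41 ± 0.68 (0.94 to 3.71 over the alternatives, higher in 20 of 30 libraries, no p from DESeq2) and Oxtr 2.86 ± 0.19, and lowest Mfsd2a -5.76 ± 0.36, Dio2 -4.01 ± 0.24 and Ifi27l2a -2.92 ± 0.13. Ttr is a hepatocyte gene, and Alb exceeded 10 times the BAT median in 2 of 30 EODR libraries (up to 393 CPM) and in 0 of 30 AL libraries. Dio2 averaged 13.9 ± 10.6 CPM in EODR and 220 ± 135 in AL, lower in 30 of 30 libraries (adjusted p = 1.9e-30). Glucocorticoid-responsive genes fell: 1 of 15 rose and 13 fell, median -0.99 (adjusted p = 8.6e-10, adjusted p = 0.036 with an estimated correlation), with Klf15 -1.85 ± 0.11 and Mt2 -1.85 ± 0.12. De novo lipogenesis genes rose: 17 of 20 rose and 3 fell, median 0.61 (adjusted p = 5.7e-07, adjusted p = 0.21 with an estimated correlation), with Fads2 1.3 ± 0.09 and Scd2 1.14 ± 0.30.

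EODF against AF compared equal hours of fasting with and without 15 earlier cycles. In liver 6099 genes differed (3009 up and 3090 down, 934 by at least 1.5-fold). The top of the ranking was Cyp2b9 6.82 ± 0.49, Fmo3 4.22 ± 0.36 and Chrna4 3.98 ± 0.45 (2.08 to 4.14 over the alternatives) and the bottom Serpina1e -4.16 ± 0.24, Selenbp2 -2.41 ± 0.20 and Serpina12 -2.39 ± 0.27. The flavin monooxygenase gene Fmo3 (ENSMUSG00000026691, chromosome 1, 162953800 to 162984528) averaged 19 ± 24.5 CPM in EODF and 0.754 ± 1.03 in AF, higher in 27 of 30 libraries (adjusted p = 3.3e-20). ER chaperone and heat shock genes were lower in EODF: 0 of 20 rose and 19 fell, median -0.61 (adjusted p = 3.7e-12, adjusted p = 0.043 with an estimated correlation), with Hsph1 -0.99 ± 0.10 and Creld2 -0.87 ± 0.10. Oxidative phosphorylation genes were higher: 24 of 34 rose and 0 fell (26 and 0 adjusted over the list alone), median 0.16 (adjusted p = 1.5e-09, adjusted p = 0.21 with an estimated correlation), with Ndufb8 0.35 ± 0.04 and Sdhb 0.34 ± 0.04. In muscle 8585 genes differed (4624 up and 3961 down, 2454 by at least 1.5-fold), and 9183 (4635 up, 4548 down, 2433 by at least 1.5-fold) without the neural library. Fructose transporter Slc2a5 and 2 others were highest (Slc2a5 5.42 ± 0.54 (5.48 without the neural library, 2.12 to 5.99 over the alternatives), Klhdc7a 3.90 ± 0.90 (3.59 without the neural library, 1.22 to 4.94 over the alternatives, higher in 13 of 30 libraries, call lost with a pseudocount of 0.1 and without replicate 3 or 5) and Atp1a3 3.80 ± 0.37 (3.27 without the neural library)), and Trim63 -3.19 ± 0.13 (-3.12 without the neural library), Fbxo32 -3.04 ± 0.14 (-2.97 without the neural library) and Odf3l2 -2.74 ± 0.18 (-2.67 without the neural library) were lowest. Trim63 averaged 333 ± 141 CPM in EODF and 3840 ± 1970 in AF, lower in 30 of 30 libraries (adjusted p = 2.8e-45, adjusted p = 1.5e-59 without the neural library). These 3 lists were lower in EODF. For the FoxO list 2 of 22 rose and 19 fell, median -1.10 (adjusted p = 4.4e-17, adjusted p = 0.0056 with an estimated correlation and adjusted p = 9e-16 without the neural library). For glucocorticoid-responsive genes 1 of 14 rose and 13 fell, median -1.12 (adjusted p = 3.4e-08, adjusted p = 0.049 with an estimated correlation and adjusted p = 5.2e-07 without the neural library). For ribosome biogenesis 0 of 20 rose and 15 fell (0 and 16 adjusted over the list alone), median -0.35 (adjusted p = 1.5e-06, adjusted p = 0.045 with an estimated correlation and adjusted p = 9.2e-06 without the neural library).

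In IngWAT 12200 genes differed (5797 up and 6403 down, 4877 by at least 1.5-fold), the most of any contrast. Highest were Mogat2 4.91 ± 0.17 (3.22 to 5.04 over the alternatives), Slc2a5 4.69 ± 0.15 and Actc1 4.60 ± 0.92 (0.80 to 5.08 over the alternatives, higher in 10 of 30 libraries, call lost with limma, with a pseudocount of 0.1 and without replicate 2 or 3), and lowest Cyp2f2 -4.49 ± 0.13, Trim63 -4.44 ± 1.11 (-6.84 to -2.27 over the alternatives) and Zc3h11a -3.56 ± 0.77 (-3.89 to -1.23 over the alternatives, call lost without replicate 2). Actc1 and Trim63 are muscle-fibre genes, and the Acta1 median in IngWAT was 6.28 CPM in EODF against 85.1 in AF. Transcripts of Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169) averaged 86.9 ± 66.5 CPM in EODF and 5.75 ± 8.69 in AF, higher in 30 of 30 libraries (adjusted p = 2.5e-56). De novo lipogenesis genes were higher in EODF: 19 of 20 rose and 0 fell, median 2.21 (adjusted p = 5.5e-19, adjusted p = 0.037 with an estimated correlation), with Elovl6 4.10 ± 0.14 and Acly 3.92 ± 0.13. Cholesterol biosynthesis genes were also higher: 21 of 23 rose and 0 fell, median 1.53 (adjusted p = 7.7e-14, adjusted p = 0.078 with an estimated correlation), with Fdps 3.26 ± 0.10 and Lss 2.67 ± 0.10. In BAT 8947 genes differed (4530 up and 4417 down, 2346 by at least 1.5-fold). The ratios were largest for Actc1 5.19 ± 0.37, Slc2a5 4.07 ± 0.15 and Atp4b 4.05 ± 0.19 (2.30 to 4.30 over the alternatives) (Actc1 4.52 with skeletal muscle markers as a covariate), and smallest for Mfsd2a -3.0 ± 0.30, Slc7a8 -2.75 ± 0.14 and Mt2 -2.73 ± 0.12. Metallothionein gene Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) averaged 24.4 ± 6.26 CPM in EODF and 205 ± 130 in AF, lower in 30 of 30 libraries (adjusted p = 7.1e-43). Higher lists were de novo lipogenesis (16 of 20 rose and 1 fell, median 1.17 (adjusted p = 4.8e-17, adjusted p = 0.029 with an estimated correlation)) and extracellular matrix and fibroblast genes (18 of 20 rose and 0 fell, median 0.87 (adjusted p = 2.4e-12, adjusted p = 0.078 with an estimated correlation)), with Col3a1 1.72 ± 0.10 and Col6a2 1.61 ± 0.07. Lower lists were glucocorticoid-responsive genes (1 of 15 rose and 13 fell (1 and 14 adjusted over the list alone), median -0.97 (adjusted p = 7.7e-10, adjusted p = 0.036 with an estimated correlation)) and the FoxO list (1 of 22 rose and 17 fell (2 and 18 adjusted over the list alone), median -0.62 (adjusted p = 1.5e-09, adjusted p = 0.019 with an estimated correlation)).

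EODR against AR compared equal hours of refeeding with and without earlier cycles. In liver 2569 genes differed (1270 up and 1299 down, 386 by at least 1.5-fold), the fewest of any contrast. Rises were Cyp2b9 5.49 ± 0.44, Fmo3 4.52 ± 0.39 (2.48 to 5.23 over the alternatives) and Scd1 2.29 ± 0.16, and falls Serpina1e -3.76 ± 0.23, Apoa4 -2.82 ± 0.17 and Selenbp2 -2.44 ± 0.20. The desaturase gene Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407709) averaged 7480 ± 3750 CPM in EODR and 1780 ± 1920 in AR, higher in 30 of 30 libraries (adjusted p = 1.5e-23). De novo lipogenesis genes were higher in EODR: 16 of 20 rose and 0 fell, median 0.65 (adjusted p = 5.1e-16, adjusted p = 0.043 with an estimated correlation), with Pnpla3 2.77 ± 0.30 and Thrsp 1.25 ± 0.25. Extracellular matrix and fibroblast genes were higher: 15 of 19 rose and 0 fell, median 0.51 (adjusted p = 2.9e-14, adjusted p = 0.058 with an estimated correlation), with Col1a1 1.11 ± 0.17 and Postn 1.08 ± 0.15. In muscle 8995 genes differed (4736 up and 4259 down, 2818 by at least 1.5-fold), and 9615 (5040 up, 4575 down, 2813 by at least 1.5-fold) without the neural library. Myosin binding protein H and cardiac actin led the rises (Mybph 4.37 ± 0.23, Actc1 4.29 ± 0.23 and Nmrk2 2.82 ± 0.19), with Fbxo32 -3.92 ± 0.15, Hspa1a -3.24 ± 0.17 and Hspa1b -3.15 ± 0.17 lowest. Expression of Mybph (ENSMUSG00000042451, chromosome 1, 134193448 to 134201232) averaged 535 ± 160 CPM in EODR and 33.8 ± 20.6 in AR, higher in 30 of 30 libraries (adjusted p = 7e-37). Oxidative phosphorylation genes were higher: 33 of 34 rose and 0 fell, median 0.43 (adjusted p = 2.7e-09, adjusted p = 0.54 with an estimated correlation), with Sdhd 0.77 ± 0.06 and Cyc1 0.70 ± 0.07, while the mitochondrial share of counts was 6.72% in EODR and 8.07% in AR. Ribosome biogenesis genes were lower: 2 of 20 rose and 18 fell, median -0.52 (adjusted p = 2.4e-07, adjusted p = 0.036 with an estimated correlation), with Gnl3 -1.01 ± 0.07 and Ncl -0.78 ± 0.10.

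In IngWAT 9181 genes differed (4545 up and 4636 down, 2142 by at least 1.5-fold). The largest ratios were Lctl 2.72 ± 0.14, Scd3 2.18 ± 0.13 and Scd1 2.14 ± 0.11, and the smallest Ifi27l2a -3.20 ± 0.11, Cyp2f2 -2.99 ± 0.13 and Pon1 -2.36 ± 0.15. Interferon-inducible gene Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) averaged 66.5 ± 19.4 CPM in EODR and 775 ± 262 in AR, lower in 30 of 30 libraries (adjusted p = 1e-53). For cholesterol biosynthesis 18 of 23 rose and 2 fell, median 0.46 (adjusted p = 4.2e-07, adjusted p = 0.28 with an estimated correlation), with Tm7sf2 1.26 ± 0.07 and Mvd 1.19 ± 0.11. For oxidative phosphorylation 25 of 34 rose and 0 fell (26 and 0 adjusted over the list alone), median 0.31 (adjusted p = 7.2e-06, adjusted p = 0.71 with an estimated correlation), with Ndufa10 0.67 ± 0.07 and Ndufa1 0.60 ± 0.08 (mitochondrial share 14.7% in EODR, 9.05% in AR). In BAT 9049 genes differed (4315 up and 4734 down, 2059 by at least 1.5-fold). Upward, the ratios were Actc1 2.85 ± 0.33, Ptgds 2.32 ± 0.22 and Cdsn 2.26 ± 0.17, and downward Dio2 -3.02 ± 0.23, Mfsd2a -2.41 ± 0.36 (-2.68 to -1.33 over the alternatives) and Ifi27l2a -2.39 ± 0.12. Prostaglandin synthase gene Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046) averaged 21.9 ± 17.2 CPM in EODR and 4.99 ± 3.61 in AR, higher in 30 of 30 libraries (adjusted p = 6.6e-17). Oxidative phosphorylation genes were higher: 32 of 34 rose and 0 fell, median 0.30 (adjusted p = 1.2e-13, adjusted p = 0.28 with an estimated correlation), with Ndufa10 0.72 ± 0.05 and Uqcrc1 0.61 ± 0.05. Mitochondrial fatty acid oxidation genes were higher: 16 of 18 rose and 0 fell, median 0.40 (adjusted p = 1.8e-10, adjusted p = 0.21 with an estimated correlation), with Acaa2 0.76 ± 0.06 and Acads 0.72 ± 0.06. The mitochondrial share was 22.9% in EODR and 16.9% in AR, and the Acta1 median 714 CPM against 1770.

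EODR against EODF compared the feeding day with the fasting day of the same cycle. In liver 8175 genes differed (3960 up and 4215 down, 1586 by at least 1.5-fold). Rises were largest for Tubb2b 4.88 ± 0.78 (2.42 to 7.29 over the alternatives, call lost without replicate 5), Fasn 2.69 ± 0.23 and Angptl8 2.60 ± 0.21, and falls for Mt2 -2.80 ± 0.34, Mt1 -2.80 ± 0.29 and Rab30 -2.24 ± 0.19. Fatty acid synthase, Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), averaged 1120 ± 712 CPM in EODR and 263 ± 392 in EODF, higher in 26 of 30 libraries (adjusted p = 1.9e-19). ER chaperone and heat shock genes rose: 15 of 20 rose and 3 fell, median 0.86 (adjusted p = 3.8e-09, adjusted p = 0.085 with an estimated correlation), with Sdf2l1 2.03 ± 0.12 and Manf 1.48 ± 0.10. PPAR target genes fell: 1 of 19 rose and 18 fell, median -0.88 (adjusted p = 5.1e-08, adjusted p = 0.28 with an estimated correlation), with Fgf21 -3.01 ± 0.32 and Pdk4 -1.89 ± 0.20. In muscle 6838 genes differed (2423 up and 4415 down, 1695 by at least 1.5-fold), and 6634 (3295 up, 3339 down, 1133 by at least 1.5-fold) without the neural library. The highest ratios (without the neural library in brackets) were Angptl8 2.94 ± 0.38 (2.89), Nmrk2 1.86 ± 0.18 (1.83) and Tnfaip2 1.84 ± 0.19 (1.81). The lowest were Pdk4 -4.92 ± 0.19 (-4.95), Chac1 -3.68 ± 0.22 (-3.70) and Pck1 -3.47 ± 0.43 (-3.50). All were still called with the tissue marker covariate. Pyruvate dehydrogenase kinase, Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), averaged 74.5 ± 58.2 CPM in EODR and 1870 ± 829 in EODF, lower in 30 of 30 libraries (adjusted p = 2.9e-47, adjusted p = 2.9e-57 without the neural library). Glucocorticoid-responsive genes fell: 0 of 14 rose and 13 fell, median -0.94 (adjusted p = 4e-12, adjusted p = 0.018 with an estimated correlation and adjusted p = 4.2e-13 without the neural library). Cholesterol biosynthesis genes rose: 16 of 23 rose and 0 fell, median 0.36 (adjusted p = 7.7e-08, adjusted p = 0.26 with an estimated correlation and adjusted p = 2.7e-09 without the neural library).

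In IngWAT 9137 genes differed (4489 up and 4648 down, 2528 by at least 1.5-fold). Angptl8 was again highest (Angptl8 3.61 ± 0.16, Ppp1r3b 2.82 ± 0.15 and Hephl1 2.81 ± 0.17), and Pck1 -3.29 ± 0.11, Pdk4 -3.02 ± 0.17 and Mycl -3.02 ± 0.20 were lowest. The gene Angptl8 (ENSMUSG00000047822, chromosome 9, 21835510 to 21837347) averaged 187 ± 52.8 CPM in EODR and 15 ± 4.84 in EODF, higher in 30 of 30 libraries (adjusted p = 7.3e-44). Cholesterol biosynthesis genes rose: 20 of 23 rose and 0 fell, median 0.94 (adjusted p = 1.5e-15, adjusted p = 0.058 with an estimated correlation), with Mvd 2.43 ± 0.12 and Ldlr 2.23 ± 0.09. Ribosome biogenesis genes rose: 14 of 20 rose and 2 fell, median 0.38 (adjusted p = 1.4e-05, adjusted p = 0.14 with an estimated correlation), with Nop58 0.68 ± 0.06 and Nop2 0.60 ± 0.04. In BAT 9942 genes differed (4671 up and 5271 down, 2910 by at least 1.5-fold). Among the rises were Pcdhgb8 3.40 ± 1.23 (0.39 to 3.80 over the alternatives, higher in 21 of 30 libraries, call lost with limma, with a pseudocount of 0.1, with the tissue marker covariate and without replicate 1, 3 or 4), Hephl1 3.19 ± 0.21 and Angptl8 2.99 ± 0.12, and among the falls Mycl -3.56 ± 0.18, Irf4 -3.17 ± 0.18 and Cyp2b10 -2.78 ± 0.23. Interferon regulatory factor 4, Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976), averaged 8.23 ± 2.57 CPM in EODR and 75.3 ± 47.7 in EODF, lower in 30 of 30 libraries (adjusted p = 7.3e-33). For cholesterol biosynthesis 20 of 23 rose and 1 fell, median 0.81 (adjusted p = 6.4e-12, adjusted p = 0.074 with an estimated correlation), with Mvd 2.47 ± 0.12 and Ldlr 2.27 ± 0.09. For glucocorticoid-responsive genes 1 of 15 rose and 13 fell, median -0.81 (adjusted p = 6.4e-07, adjusted p = 0.08 with an estimated correlation), with Ddit4 -1.88 ± 0.13 and Cdkn1a -1.64 ± 0.10.

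The 22 gene lists asked which processes and cell types moved. Of 616 list tests, 225 were called (112 up and 113 down), 22 of them also with an estimated correlation. Calls up and down of 28 tests per list were 9 and 5 for PPAR target genes, 8 and 7 for mitochondrial fatty acid oxidation, 18 and 5 for de novo lipogenesis, 15 and 6 for cholesterol biosynthesis, and 2 and 1 for gluconeogenesis and amino acid catabolism. They were 9 and 13 for FoxO, ubiquitin ligase and autophagy genes, 6 and 16 for glucocorticoid-responsive genes, 4 and 8 for ER chaperones and heat shock proteins, and 1 and 0 for ATF4 and amino acid response. Ribosome biogenesis had 8 and 11, oxidative phosphorylation 12 and 6, cell cycle 5 and 4, extracellular matrix and fibroblast genes 11 and 8, thermogenesis and brown adipocyte genes 0 and 4, and lipolysis and adipocyte genes 1 and 0. Core clock genes had 0 and 1, and bile acid synthesis and transport 0 and 0. Among marker lists of other cell types, macrophage had 0 and 8, lymphocyte 0 and 6, erythroid 3 and 2, hepatocyte 0 and 2, and skeletal muscle 0 and 0. A list called in 1 contrast or tissue and not in another was not tested for the difference. In muscle, 50 of 154 list tests were called with the neural library and 55 without it.

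**Figure D2:**
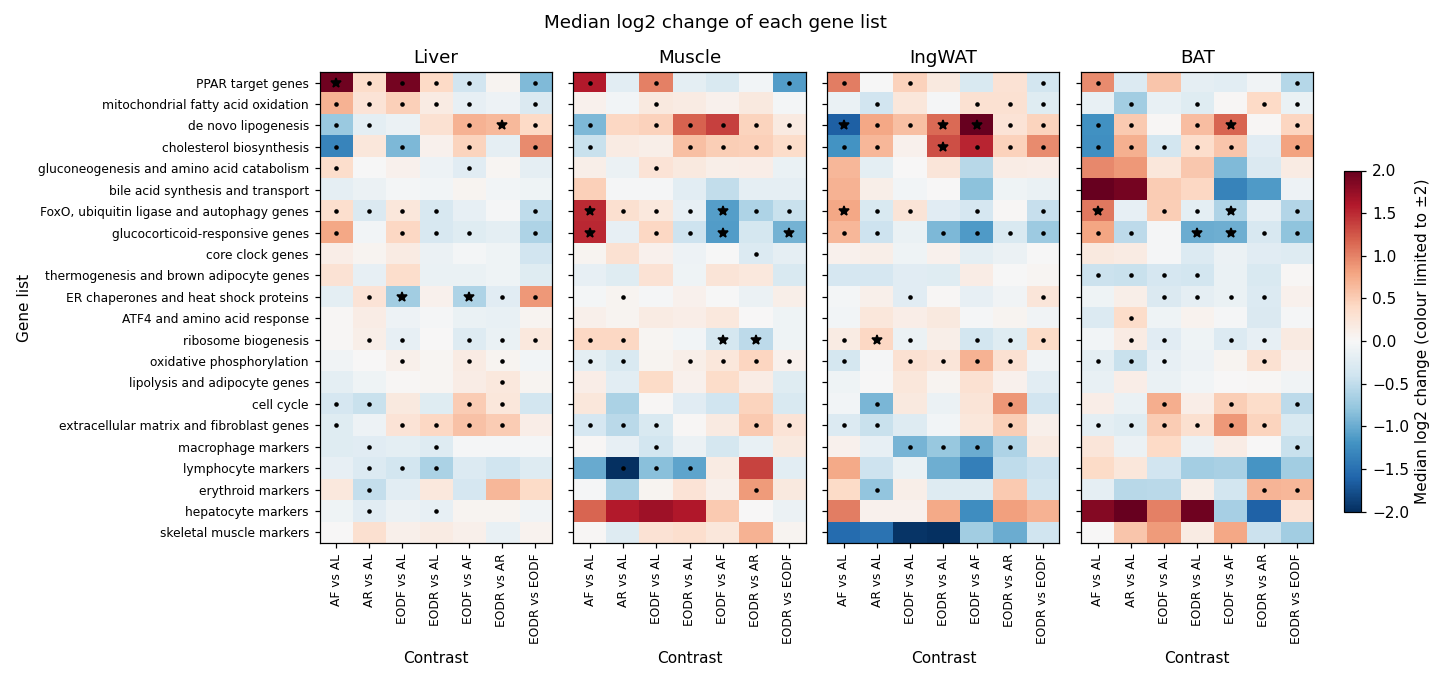
Median log2 ratio of each gene list (colour) by contrast and tissue. Dots mark calls with the preset correlation, and stars mark the calls that also held with an estimated correlation (22 of 616).

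The time course asked when each regimen left AL. Counts of genes that differed from AL at 4, 8, 12, 16, 20 and 24 h, with 5 libraries per group, were as follows. Liver AF had 1267, 6045, 6225, 549, 3590 and 3697, and AR 3516, 1977, 5055, 2054, 3846 and 1526. Liver EODF had 3750, 3534, 6858, 1063, 3246 and 3315, and EODR 3375, 3225, 3995, 871, 3066 and 2181. The liver AF, EODF and EODR series had their lowest count at 16 h (ZT4). All regimens were compared with the same 5 AL libraries at each time. A low or high count shared by series can thus come from the AL group. In muscle AF the counts rose from 996 at 4 h to 6655 at 24 h (1844 and 7481 without the neural library), the 4 h count running from 193 to 1381 with 1 replicate number left out (455 with the tissue marker covariate, 649 with no filter). Muscle AR went from 5484 at 4 h to 5239 at 24 h (6353 and 6144 without it). Muscle EODF had 544, 3988, 858, 1047, 1722 and 1585, and 1085, 3591, 1541, 1663, 2649 and 2302 without the neural library. For its 8 h count chance is not excluded: with the library, 30 of 100 splits gave as many genes in the limma form. Muscle EODR had 1758, 1612, 660, 885, 2638 and 796, and 2736, 2805, 1132, 1474, 3827 and 1420 without the neural library. IngWAT AF rose from 990 at 4 h to 6272 at 8 h and had 5913 at 24 h. IngWAT AR had 2566 to 4444, EODF had 6235, 5832, 6957, 4555, 2945 and 2970, and EODR ranged from 2959 to 6423. BAT AF had 5572 to 7282, AR 2799 to 5547, EODF 3534 to 5762 and EODR 1956 to 7318. Leaving out 1 replicate number moved 38 of these 96 counts by over 1.5 times, among them liver EODF at 16 h (379 to 1264) and liver EODR at 8 h (1659 to 2982), 12 h (2189 to 3801) and 20 h (1681 to 3277). The difference between times was not tested.

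**Figure D3:**
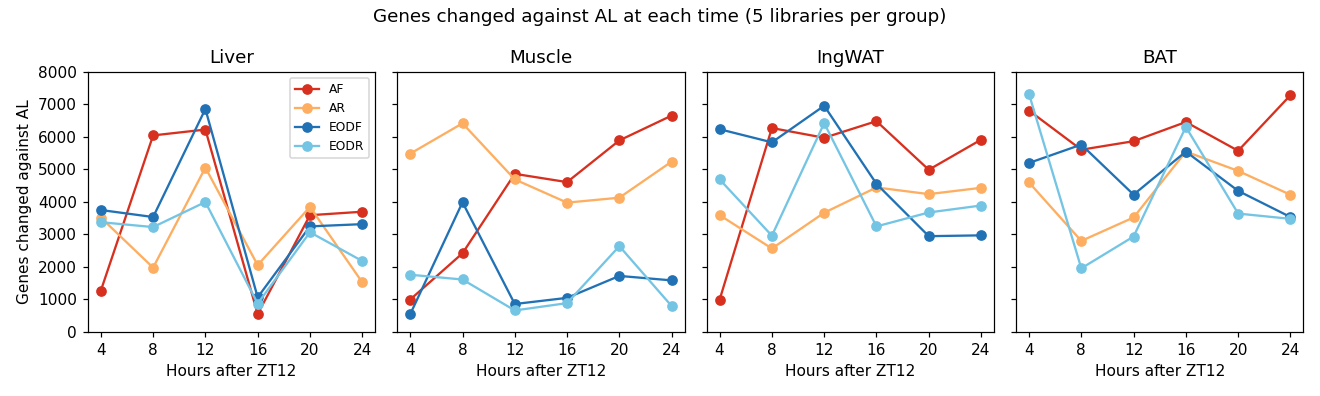
Genes that differed from AL (vertical axis) against hours after ZT12 (horizontal axis) for AF, AR, EODF and EODR in each tissue, 5 libraries per group. Muscle AF climbs from 996 to 6655 genes, and IngWAT EODF goes from 6235 to 6957 at 12 h and 2970 at 24 h.

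De novo lipogenesis in IngWAT separated the fasts over time. Its median ratio to AL at 4, 8, 12, 16, 20 and 24 h was -0.46, -1.86, -1.48, -1.90, -2.05 and -2.05 in AF. In EODF it was 1.24, 0.51, 0.84, 0.56, 0.35 and 0.47.

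Sampling over 24 h asked how feeding changed daily rhythms. A 24 h rhythm was called in 7496 (AL), 6898 (AF), 5101 (AR), 5596 (EODF) and 7185 (EODR) liver genes. Muscle had 3639, 7434, 6551, 6105 and 3766 (4893, 8580, 7560, 6069 and 4927 without the neural library). The muscle AL count ran from 2001 to 3731 with 1 replicate number left out. IngWAT had 7828, 9445, 9106, 9349 and 8206, and BAT 8075, 10776, 8007, 7592 and 10884. In the fasted and refed regimens time of day and hours of fasting or refeeding run together, so these counts hold both. A rhythm different from AL was called in 4411 (AF), 3712 (AR), 4401 (EODF) and 2421 (EODR) liver genes, and in 3850, 2883, 2014 and 235 muscle genes. The muscle counts were 4917, 3756, 903 and 413 without the neural library. IngWAT had 3566, 1841, 4529 and 1582, and BAT 7012, 3905, 4008 and 3640. Leaving out 1 replicate number moved 14 of these 16 by over 1.5 times, as in liver AR (1753 to 3090), muscle EODF (350 to 1800) and muscle EODR (90 to 258), the exceptions being BAT AF and EODF. Among genes rhythmic in both regimens the median peak in AF was 2.9 h later than in AL in liver, 1.8 h in muscle, 1.6 h in IngWAT and 2.6 h in BAT. In EODR it moved by -1.7 h in liver, -1.5 h in muscle and -0.5 h in IngWAT (earlier), and by 0.9 h in BAT (later).

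Of 19 core clock genes, the rhythm differed from AL in 11 (AF), 1 (AR), 14 (EODF) and 14 (EODR) in liver. The numbers were 13, 5, 11 and 11 in muscle (13, 8, 10 and 13 without the neural library), 16, 7, 16 and 15 in IngWAT, and 14, 11, 12 and 15 in BAT. Over the settings the liver AR number ran from 0 to 2, and with 1 replicate number left out the muscle EODF number ran from 6 to 11. In EODR, Arntl (Bmal1) peaked earlier than in AL, by -3.1 h (95% interval -3.5 to -2.7) in liver, -4.8 h (-5.2 to -4.4) in muscle, -4.2 h (-4.4 to -3.9) in IngWAT and -3.7 h (-4.2 to -3.2) in BAT. Dbp moved by -3.4, -5.1, -4.3 and -4.8 h. In AF both moved later, Arntl by 1.4, 2.7, 2.9 and 4.5 h and Dbp by 1.8, 4.7, 3.7 and 4.6 h. The log2 amplitude of Dbp in EODF was 1.68 ± 0.20 (SE) against 3.20 ± 0.06 in AL in liver, 1.33 ± 0.15 against 3.0 ± 0.09 in IngWAT and 0.88 ± 0.10 against 2.58 ± 0.11 in BAT. Muscle EODF phases and amplitudes include the neural library and are left out.

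**Figure D4:**
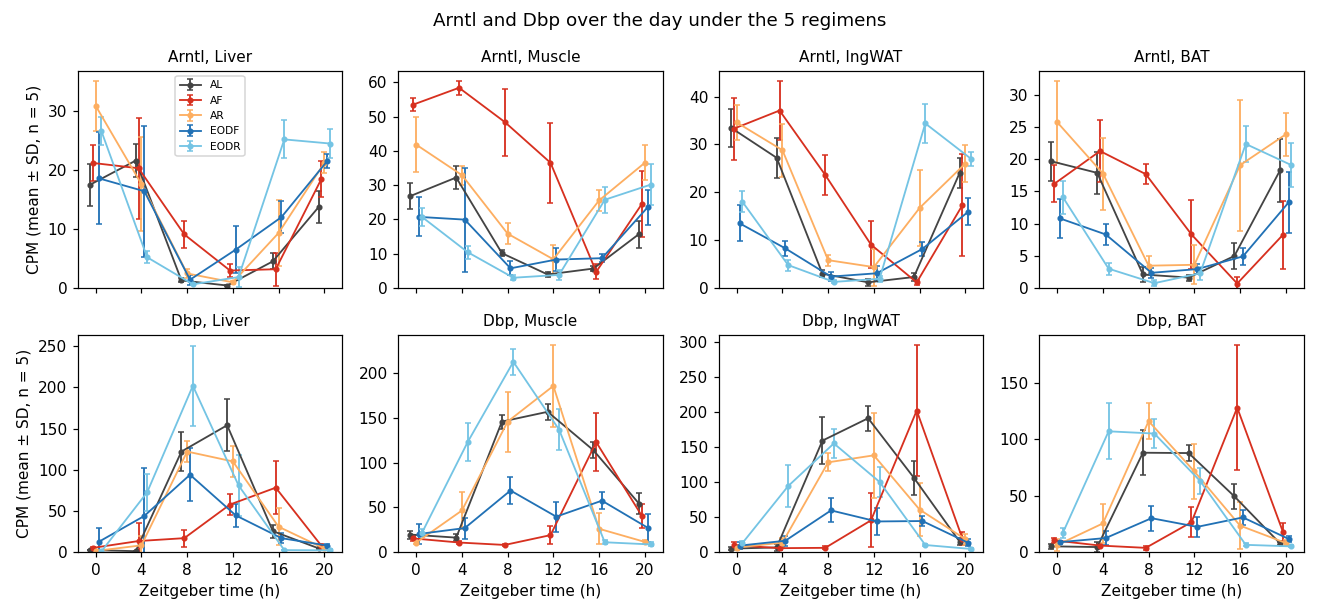
CPM of Arntl and Dbp (mean ± SD, n = 5) against Zeitgeber time in the 5 regimens and 4 tissues. The EODR curves lead the AL curves, by 3.1 to 4.8 h for Arntl.

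The 4 tissues were compared for genes that moved the same way in each, among 12224 genes tested in all. AF raised 955 genes in all 4 tissues (105 expected from independent lists) and lowered 829 (88 expected). AR raised 504 (74.7 expected) and lowered 374 (54.5), EODF raised 378 (65.7) and lowered 155 (32.2), and EODR raised 331 (50.9) and lowered 330 (54.2). Between fasts, 581 were higher in EODF than in AF (79.5 expected) and 583 lower (85.5). Between refeedings, 230 were higher in EODR than in AR (26.1) and 157 lower (28.2), and in all 235 without replicate 1 and 229 without replicate 2, against 387. From EODF to EODR, 443 rose (51.2) and 842 fell (116). AF lowered 16 of 23 cholesterol biosynthesis genes and 12 of 20 de novo lipogenesis genes in all 4 tissues, and raised 10 of 13 PPAR target genes. EODF was above AF in 12 of 20 de novo lipogenesis genes. From EODF to EODR, 15 of 23 cholesterol biosynthesis genes rose, and 11 of 21 FoxO genes, 8 of 13 PPAR target genes and 8 of 13 glucocorticoid-responsive genes fell. In EODR, 8 of 13 glucocorticoid-responsive genes were below AL in all 4 tissues. Muscle enters these counts with the neural library.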

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

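Chosen only after the result was seen were the tests of neural markers, of the group mates and of Acta1 for the muscle library, the tests of adipocyte share and of food eaten before the fast in IngWAT, and the tests with other splits of the libraries. The root mean square log2 distance of a library from its group's median set 1 library apart from its 4 group mates, by Dixon's ratio at 0.71, in 20 of 120 groups (16.7%), where chance gives about 5%. In liver these were AL ZT16 library 5 (0.404), AL ZT20 library 5 (0.332), AR ZT12 library 5 (0.579) and EODR ZT16 library 1 (0.339). In muscle they were AL ZT0 library 3 (0.326), AF ZT20 library 3 (0.539), EODF ZT20 library 1 (1.91), EODF ZT4 library 5 (0.558) and EODR ZT8 library 1 (0.337). IngWAT had AL ZT0 library 4 (0.616), AL ZT4 library 3 (0.472), AF ZT4 library 5 (0.736), EODF ZT16 library 5 (0.47), EODF ZT0 library 2 (0.496), EODR ZT16 library 5 (0.669) and EODR ZT4 library 3 (0.544). BAT had AF ZT4 library 5 (0.482), EODF ZT20 library 2 (0.748), EODF ZT8 library 1 (0.469) and EODR ZT4 library 5 (0.448). The median of the group includes the library itself, and distances are not normal values, so the share due to chance is approximate. Total counts set 1 library apart in 9 of 120 groups (7.5%). These were muscle AR ZT20 library 5 (63.7M counts), AR ZT12 library 3 (55.2M) and EODF ZT8 library 3 (77.2M), IngWAT AF ZT4 library 4 (58.8M) and AR ZT16 library 1 (68.8M), and BAT AL ZT20 library 4 (77.9M), AF ZT12 library 5 (68.3M), EODF ZT20 library 3 (62.7M) and EODR ZT8 library 2 (56.1M). No item of 296 moved 1 way in every library of 1 tissue and the other way in every library of another.

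The first pattern weighed is the muscle library EODF ZT20 library 1, at 1.91 from its group's median where the next largest muscle distance was 0.566. RNA of neural tissue has what it needs: 20 of 20 neural markers were at least 10-fold above the median of the other muscle libraries (6 of the 20 have a median of at least 1 CPM in muscle). The list was not blind, since 7 of its genes (Kif5a, Aldoc, Nefl, Nefm, Sv2a, Slc17a7 and Gad1) had already been seen high in this library against its group mates. The most abundant were Kif5a (2640 CPM), Syp (1630), Camk2a (1480) and Mbp (1260). A library wholly of another tissue remains open as the form of it, since Acta1 was at 0.43% of the median, Ckm at 0.403%, Actn3 at 0.45% and Myh4 at 0.492%. The tables argue against the EODF regimen at this time, since 0 of the neural markers were 10-fold up in each of the other 4 libraries of the group. Whether a sample was exchanged before or after extraction cannot be read from the tables. Of 100 splits of the 10 libraries of EODF and AL at ZT20 in muscle, 30 gave as many genes as the real split (3075 genes, highest other 6656), so chance is not excluded for that count. The splits were not repeated without this library. That is the limma form of the test. In edgeR, EODF against AL at ZT20 gave 3988 genes with this library and 3591 without it.

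The second pattern is the earlier peak of clock genes in EODR, with Arntl moved by -3.1 to -4.8 h. If the EODR hours were stated 4 h too early, all rhythmic genes would line up with AL better when moved 4 h later. Over genes rhythmic in AL and outside the clock list, the correlation across genes and times of EODR with AL changed by -0.49 ± 0.13 (SE) in muscle, -0.33 ± 0.08 in IngWAT and -0.38 ± 0.05 in BAT, which argues against a wrong hour in these tissues. In liver the change was 0.03 ± 0.05, from 0.50 to 0.53, which leaves a wrong hour open there. The 19 clock genes alone went from r = 0.51, 0.42, 0.42 and 0.32 (liver, muscle, IngWAT, BAT) to 0.92, 0.81, 0.90 and 0.85 when moved. A different response of the clock genes to the feeding cycle, which the design names, may remain as the explanation in muscle, IngWAT and BAT, and is a hypothesis found on the same data.

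The third pattern is the rise of de novo lipogenesis genes above AL on the fasting day in IngWAT, at a median of 0.60, a list call that was lost with an estimated correlation (adjusted p = 0.33 with an estimated correlation). Interchanged EODF and EODR columns would make EODR against EODF resemble AF against AL. Over 1063 genes changed at least 2-fold in AF and outside both lipid lists, the correlation across genes was -0.63 ± 0.016, which argues against it. A larger share of adipocyte RNA would raise adipocyte genes alike, and the lipogenesis median exceeded the adipocyte median by 0.37 ± 0.09 (0.60 against 0.23), which argues against that as the whole cause. Food eaten before the fast began was expected to have faded by 24 h, when the median was still 0.47 ± 0.21 above AL, which argues against it as the whole cause. The median fell from 1.24 at 4 h to 0.35 at 20 h, so that food stays open as a cause in part or in whole. An adaptation to the repeated cycles is a candidate explanation, which no test here addressed directly. A difference in age between regimens stays open, since the labels do not give age at sampling.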

How the results depend on the processing

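Chosen after seeing the data were limma on log2(CPM + 1), DESeq2, leaving out the neural library, and markers of the other tissues as a covariate (not run in liver). The 28 counts of the averaged contrasts stayed within 1.5 times under every alternative run, among them the replicate block, a pseudocount of 0.1, no filter, a filter on mean CPM, median-ratio scaling, only the 2 regimens compared and each leave-out. Of the 7 counts of genes moved alike in 4 tissues, only EODR against AR moved beyond that, to 235 without replicate 1 and 229 without replicate 2 (387 with all, and up to 322 in the other leave-outs). The 168 named genes kept their direction under every alternative. Calls were lost in 7 cases with limma (Actc1 in IngWAT EODF against AL and AF, Hist2h2aa1 in muscle EODF and EODR against AL, Klhdc7a in muscle AF against AL, Pcdhgb8 in BAT EODR against EODF, and Trim63 in IngWAT EODR against AL). With a pseudocount of 0.1 they were lost in 7 cases (the same apart from Trim63, and Klhdc7a in muscle EODF against AF), and with the covariate in 1 (Pcdhgb8). DESeq2 gave no p for 2, Alb in AR and Ttr in EODR against AL in BAT. No covariate held hepatocyte markers, so the BAT rises of Alb, Apoa1, Serpina1b and Ttr were not adjusted for hepatocyte RNA. Without replicates 1 to 5, 1, 7, 9, 4 and 4 were lost, each named beside its gene in the results. The replicate block left all 168 past the threshold. Replicate numbers carried no shared deviation (mean r of same-numbered libraries from -0.008 to 0.019), so they were not treated as paired.

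Of the 616 list tests, 225 were called, 22 with an estimated correlation (203 weaker) and 377 with fry (155 stronger, 3 weaker). The estimated correlation allows for genes of a list varying together, and fry does not compare a list with other genes. Other settings called 234 (pseudocount of 0.1), 226 (median-ratio scaling), 226 (replicate block) and 222 to 234 (leaving out a replicate number). A single test reversed: mitochondrial fatty acid oxidation in muscle, EODR against EODF, not called with all libraries (adjusted p = 0.96, upward), was called downward without replicate 1 (adjusted p = 0.014). That number holds the neural library, and without this library alone the adjusted p was 0.23. Over the 5 leave-outs the adjusted p ran from 0.014 to 0.92.

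With 1 replicate number left out, counts at single times moved beyond 1.5 times in the groups given here as lowest to highest. In liver these were AF at ZT16 691 to 952 and ZT4 276 to 497, AR at ZT20 1299 to 1625, ZT0 3223 to 5063, ZT4 1160 to 2762, ZT8 2081 to 3824 and ZT12 902 to 1421, EODF at ZT4 379 to 1264 and ZT12 2195 to 2766 and EODR at ZT20 1659 to 2982, ZT0 2189 to 3801, ZT4 525 to 786, ZT8 1681 to 3277 and ZT12 1412 to 1965. In muscle these were AF at ZT16 193 to 1381 and ZT20 1533 to 2428, EODF at ZT16 196 to 714, ZT20 2510 to 4031, ZT0 355 to 851, ZT4 298 to 1202, ZT8 728 to 1523 and ZT12 913 to 1607 and EODR at ZT16 691 to 2108, ZT20 678 to 2130, ZT0 223 to 907, ZT4 407 to 685, ZT8 1066 to 3463 and ZT12 237 to 931. In IngWAT these were AF at ZT16 519 to 1149, AR at ZT20 1262 to 2567, EODF at ZT8 1855 to 2445 and ZT12 1838 to 2504 and EODR at ZT16 3056 to 4376, ZT0 4234 to 5857, ZT8 2447 to 3304 and ZT12 2285 to 3655. In BAT these were EODF at ZT12 2337 to 3117 and EODR at ZT0 1745 to 2519. In most of these muscle groups the highest count came without replicate 1, which holds the neural library; elsewhere no cause beyond the loss of libraries was tested. With no filter on low values counts moved to liver AF at ZT4 329, muscle AF at ZT16 649, EODF at ZT16 334, ZT0 518, ZT4 526 and ZT8 1118 and EODR at ZT16 1130, ZT20 983, ZT4 558 and ZT12 445 and IngWAT AF at ZT16 649 (in muscle 36442 genes were then tested, against 14346), and the cause was not tested further. Without the neural library they moved to muscle AF at ZT16 1844, EODF at ZT16 1085, ZT0 1541, ZT4 1663 and ZT8 2649 and EODR at ZT16 2736, ZT20 2805, ZT0 1132, ZT4 1474 and ZT12 1420. With the covariate, muscle AF at ZT16 moved to 455, and the cause was not tested.

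Genes with a rhythm in muscle AL ranged from 2001 to 3731 over the leave-outs. Genes whose rhythm differed from AL ranged over liver AF 2646 to 4075, AR 1753 to 3090, EODF 2687 to 4190 and EODR 1492 to 2008, muscle AF 2345 to 3412, AR 1501 to 2588, EODF 350 to 1800 and EODR 90 to 258, IngWAT AF 2215 to 3104, AR 1105 to 1581, EODF 2824 to 4147 and EODR 737 to 1115 and BAT AR 2380 to 3212 and EODR 1854 to 3276. They were muscle EODF 734 and IngWAT EODR 969 with limma, muscle EODF 673 and IngWAT EODR 933 with a pseudocount of 0.1, and muscle EODF 903 and muscle EODR 413 without the neural library. For limma and the pseudocount the cause was not tested in IngWAT. In muscle EODF both, like leaving out the library, fell far below the 2014 of the chosen test. Clock genes whose rhythm differed in liver AR numbered 2 with limma, 2 with a pseudocount of 0.1, 0 with no filter and 0 to 1 over the leave-outs, against 1. In muscle AR they numbered 8 without the neural library, and in muscle EODF 6 to 11 over the leave-outs.

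In muscle EODF against AL, 3129 genes were up and 2082 down, and 2771 and 2808 without the neural library. From EODF to EODR in muscle, 2423 were up and 4415 down, and 3295 and 3339 without it. Depth, at least 42908266 counts per library, was not varied. In the simulated liver data 9 of 50 genes changed 1.2-fold were recovered, and 1 of 50 rhythm differences of amplitude 0.2. Genes below 1 CPM in AL gave ratios that depend on the pseudocount, such as Fmo3 in liver EODF against AL (6.6, and 5.3 with a pseudocount of 0.1 and 3.37 with limma).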

Other observations

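The tests with other splits of the libraries were all chosen after the results were seen. For each count 100 splits were compared, the real split among them. In the 28 averaged contrasts only the real split (1 of 100) gave as many genes, with 2558 to 12165 genes against at most 5181 in any other split. For genes changed alike in 4 tissues the same held in 7 of 7 (376 to 1767, highest other 57), and for rhythm within a regimen in 20 of 20 (3509 to 10505, highest other 3027). At single times it held in 95 of 96, the exception being muscle EODF at ZT20 (30 of 100). Of the 16 rhythm differences it held in 14. In muscle AR 2 of 100 splits gave as many (2603 real, highest other 2754), as did 2 of 100 in IngWAT AR (1284 real, highest other 1696). Splits that exchange few libraries keep part of the difference between regimens, so a high count in another split was not read further.

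Markers of other tissues were counted after the first results were seen. Alb in BAT was above 10 times its median of 2.44 CPM in 5 AR, 3 AF, 2 EODF and 2 EODR libraries and in 0 AL libraries of 30 each, with a highest value of 3760 CPM. Cd79a in IngWAT was above 10 times its median of 0.718 CPM in 1 AL, 3 AF, 2 AR, 2 EODF and 1 EODR libraries, up to 280 CPM. Slc1a2 reached 241 CPM in an IngWAT library (median 0.296). Acta1 in IngWAT had medians of 32.4 CPM in AL, 85.1 in AF, 23.4 in AR, 6.28 in EODF and 9.28 in EODR. In BAT its medians ran from 714 CPM in EODR to 1770 in AR, with a highest value of 28500 in EODF. Actc1 in BAT rose by 5.08 in EODF against AL, and by 4.34 with skeletal muscle markers as a covariate.

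The share of counts on mitochondrial genes differed with regimen. In BAT it was 23.5% in AL and 16.9% in AR, in muscle 10.6% in AL and 6.72% in EODR, and in IngWAT 9.05% in AR and 14.7% in EODR. Skeletal muscle markers in muscle had a median of 0.29 in EODF against AL and were not called with all libraries (adjusted p = 0.96, adjusted p = 0.99 with an estimated correlation). Without the neural library they had adjusted p = 5.6e-08, and an estimated correlation was not run in that setting. Each library was also correlated with the mean of every group in its tissue, its own group's mean taken without it. The closest mean was that of its own group for 120 of 150 libraries in liver, 113 in muscle, 90 in IngWAT and 102 in BAT.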
